A study of Rattus norvegicus with 15 samples.

How the data were processed

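Expression was measured on 15 Affymetrix rat gene arrays, 1 for each biochip of freshly isolated primary rat hepatocytes. Per the labels' protocols, the cells were seeded in the biochips, left to adhere for 24 h, and perfused at 25 µl/min with medium holding flutamide or its solvent. Total RNA (100 ng) was made into biotin-labelled cDNA by a whole-transcript protocol. The arrays form 3 groups: DMSO solvent (n = 5), 10 µM flutamide (n = 6) and 100 µM flutamide (n = 4), each after 24 h of exposure.

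The authors deposited 1 table of log2 expression values, 1 column per array and 1 line per probe set. The submitters' processing notes name RMA, which corrects background, quantile-normalizes arrays and summarises probes, and the Partek software. Their versions, order and settings are not given in the sources used here. The deposited log2 values had array minima of 1.80 to 2.02, maxima of 13.29 to 13.51 and medians of 5.38 to 5.51, and were not normalized further. Arrays have no read depth, so the number of arrays limits the precision. No background or detection value was used, so dim genes are described by level alone.

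Of 29214 probe sets, 15633 had an entry in the platform annotation. Of these, 323 held several genes and 15310 held 1 gene symbol, of which 15279 were matched by gene identifier to the RefSeq genes of assembly GRCr8 to update symbols. That assembly served for names only and no coordinates are printed. The 13904 probe sets without a single gene name were left out of the tests. For the 527 genes with more than 1 probe set, the one with the highest mean over all arrays was used, which left 14506 genes. No column of the table belonged to another sample (0 such columns).

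Groups were compared with limma (lmFit and eBayes, limma 3.58.1 in R 4.3.3) on the log2 values of all 15 arrays, with 11 residual degrees of freedom per gene before moderation. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all 14506 genes. The sample titles number the biochips 10 to 16 and 20 to 27. Each of these number series holds all 3 groups, and the labels do not say what they stand for. The series was fitted as a 2-level block, and values within each series are given beside the pooled ones for called lists and for part of the genes. In deviations from the group means, pairs of arrays from different groups but the same series had a median correlation of 0.0646 (37 pairs), against -0.0623 for 37 pairs from different series. The numbers within a series pair no arrays across groups.

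The 39 gene lists were written from textbook knowledge before the data were examined. They are AhR targets, CAR and PXR targets, NRF2 targets, ER stress chaperones, ATF4 and CHOP targets, p53 targets, heat shock response, apoptosis machinery, NF-kB and inflammation, acute phase proteins, respiratory complex I, respiratory complexes II to V, mitochondrial stress and chaperones, PPARalpha and fatty acid oxidation, lipogenesis, cholesterol synthesis, bile acid synthesis and transport, hepatocyte plasma proteins and regulators, complement and coagulation, urea cycle and amino acid catabolism, gluconeogenesis, glycolysis and hypoxia, androgen-related and sex-biased genes, cell cycle, conjugation enzymes, efflux and uptake transporters, cytoskeleton and dedifferentiation, proteasome, autophagy and lysosome, ribosome biogenesis, aminoacyl-tRNA synthetases, circadian clock and immediate early genes. The remaining lists hold markers of other cell types: stellate cells and fibroblasts, Kupffer cells and macrophages, endothelial cells, cholangiocytes, lymphocytes and red blood cells. They hold 1037 entries, of which 925 were measured, over 895 genes, 28 of them in more than 1 list. Lists were tested with camera at its preset inter-gene correlation of 0.01, adjusted over the 39 lists. Camera with an estimated correlation and the rotation test fry were run beside it. Members of each list were also counted after adjustment over the list alone.

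The rule for named genes was fixed before the data were examined. It takes the 8 largest rises and 8 largest falls among called genes that moved the same way in both series, up to 3 called members of each list or otherwise its member of lowest p, and a fixed set reported whatever the result, among them Cyp1a1, Cyp1a2, Cyp2b1, Cyp3a23-3a1, Cyp7a1, Hmox1, Nqo1, Ddit3, Cdkn1a, Hspa5, Alb, Hmgcs1 and Ccnd1. Hmgcs1 is not among the genes tested and is not analysed here. Because no gene was called over all genes, the text also names list members that passed after adjustment over the list alone, other members of low p, and the genes of lowest p or largest change. All of these were chosen after their values were seen.

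The tests were run on simulated data with the real gene means, residual spread and design and 14506 genes, of which 67, 67 and 66 were changed 1.5-fold, 2-fold and 4-fold in each comparison, with noise drawn independently for each gene. For 10 µM against DMSO, 52.2% of genes changed 1.5-fold, 88.1% of those changed 2-fold and 98.5% of those changed 4-fold were recovered. The shares were 58.2%, 91.0% and 98.5% for 100 µM against DMSO, and 50.7%, 89.6% and 100% for 100 µM against 10 µM. False calls numbered 8, 10 and 17 among 167, 175 and 177 calls. The independent noise leaves out the correlation between genes of the real arrays. The changed genes were drawn at random from all genes, and the noise of a gene was the same on every array. The real residual SD was 0.412 on 10 µM array 23 and 0.279 on 100 µM array 15. The shares do not hold for genes of large SE. At 10 µM the median SE was 0.11, against 0.37 for Ddit3 and 0.65 for Cyp2b1.

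The counts were also set against 100 splits, the real one included, in which group labels were exchanged at random among all arrays of the 2 groups compared, with the number series still fitted. They were also exchanged within each number series alone, which was chosen after seeing the data. For differences between the series, series labels were exchanged within each group.

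Alternatives fixed beforehand were no block, a random block, each series alone, renewed quantile normalization, median centring, leaving out genes below the 30th percentile of mean level, all probe sets, averaged probe sets, an intensity trend with a robust prior, array quality weights, fitting 2 groups alone, an adjusted p under 0.01, a minimum 1.5-fold change and leaving out each array in turn. A fit without the 3 arrays of lowest quality weight was added after seeing the data.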

Results

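Flutamide is a nonsteroidal antiandrogen whose clinical use is limited by liver injury. Its effect on transcript levels was measured in primary rat hepatocytes kept in perfused microfluidic biochips, small culture chambers under flow, after 24 h at 10 µM (6 arrays) or 100 µM (4 arrays), with DMSO as the solvent control (5 arrays). Number series 1 held 2 DMSO, 3 10 µM and 2 100 µM arrays, and number series 2 held 3, 3 and 2. By their titles the arrays come from separately numbered biochips. The labels do not say whether these hold cells of separate animals or isolations, so the p-values measure only the spread between these samples. Pairs of arrays correlated at 0.955 to 0.994, and no 2 arrays were identical. The 10 µM array 23 stood apart, with a median correlation of 0.962 with the other arrays and a quality weight of 0.205. Weights were also low for 100 µM array 15 (0.427) and 10 µM array 24 (0.549).

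The first question is what 10 µM flutamide did to these cells. Genes of fatty acid oxidation, amino acid catabolism, bile acid handling and drug metabolism lay lower than in DMSO as groups, by a mean log2 change of -0.19 to -0.28, and cell cycle genes lay higher (0.14) by camera. With an estimated correlation 0 of 39 lists were called (lowest adjusted p = 0.317 with an estimated correlation). No single gene was called. Hgd, the homogentisate dioxygenase of tyrosine breakdown, had the most negative value among list members that passed within their list, at a log2 change of -1.10 (SE 0.26, 2.14-fold lower, n = 6 against 5, adjusted p = 0.317 over all genes). That fall lay mainly in series 2, with Hgd at -0.26 within series 1 and -1.76 within series 2. At the preset correlation camera called 14 lists, 11 lower and 3 higher, and fry called 0 (lowest adjusted p = 0.170). Within series 1 alone camera called 7 lists, 2 of them lower, and within series 2 alone 16, 13 of them lower. The 7 lists called within series 1 were not among the 14 called on all arrays. The mixed form of fry, which asks for change in either direction, called 2 lists, bile acid genes and hepatocyte plasma proteins. Random splits of the same arrays called a median of 7.5 lists by camera, at most 17.

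Of 35 measured genes of PPARalpha and fatty acid oxidation, 28 were lower and 7 higher than in DMSO, with a mean log2 change of -0.19 (adjusted p = 0.000384 by camera, adjusted p = 0.380 with an estimated correlation). Over all genes 0 members passed. Adjusted over the list alone 4 passed, all lower: Decr1 (-0.51, SE 0.14) and Eci1 (-0.45, SE 0.13), auxiliary enzymes of unsaturated fatty acid oxidation, Vnn1 (-0.96, SE 0.27), a pantetheinase, and Angptl4 (-0.60, SE 0.17), a lipoprotein lipase inhibitor. Vnn1 was at -0.07 within series 1 and -1.63 within series 2. The list mean was -0.02 within series 1 and -0.31 within series 2. In the urea cycle and amino acid catabolism list 24 of 32 members were lower, with a mean of -0.28 (adjusted p = 0.000384, and adjusted p = 0.317 with an estimated correlation). Hgd, Fah (-0.73, SE 0.18), the last enzyme of tyrosine breakdown, and Kynu (-0.88, SE 0.26), the kynureninase of tryptophan breakdown, passed adjusted over the list alone. Kynu was at -0.28 within series 1 and -1.35 within series 2. The list means were -0.11 and -0.40 within series 1 and 2. Gluconeogenesis genes were lower in 12 of 14 cases, with a mean of -0.14 (adjusted p = 0.0300, adjusted p = 0.380 with an estimated correlation), -0.15 within series 1 and -0.14 within series 2. Its member of lowest p was Gys2, the liver glycogen synthase (-0.48, SE 0.21), and 0 members passed adjusted over the list alone. This call was lost without DMSO array 11 (adjusted p = 0.0650), DMSO array 21 (0.0671), or 10 µM array 12 (0.0564), 13 (0.0741) or 25 (0.0801). It was also lost after renewed quantile normalization (0.0674) and with dim genes left out (0.0670). In all of these fits the mean lay between -0.12 and -0.15.

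Bile acid synthesis and transport genes were lower in 18 of 24 cases, with a mean of -0.20 (adjusted p = 0.000737, adjusted p = 0.317 with an estimated correlation), and -0.09 and -0.29 within series 1 and 2. Slco1b2, a hepatic uptake transporter of organic anions (-0.61, SE 0.15), and Baat, which conjugates bile acids with amino acids (-0.84, SE 0.21), passed adjusted over the list alone. The efflux and uptake transporters had a mean of -0.19 with 17 of 23 members lower (adjusted p = 0.00454, adjusted p = 0.317 with an estimated correlation), 0.03 within series 1 and -0.37 within series 2. Only Slco1b2 passed adjusted over that list alone, and the call was lost without the 3 arrays of lowest quality weight (-0.10, adjusted p = 0.113). CAR and PXR targets, the genes of the main drug-sensing receptors of hepatocytes, had a mean of -0.20 with 16 of 24 lower (adjusted p = 0.00454, adjusted p = 0.380 with an estimated correlation), -0.00 within series 1 and -0.34 within series 2. The conjugation enzymes also had a mean of -0.20, with 18 of 25 lower (adjusted p = 0.00454, adjusted p = 0.317 with an estimated correlation), -0.05 and -0.32 within series 1 and 2. In both of these lists 0 members passed adjusted over the list alone, and the member of lowest p was Gsta3, a glutathione S-transferase, at -0.74 (SE 0.20), 0.01 within series 1 and -1.32 within series 2.

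Ribosome biogenesis genes were lower in 21 of 27 cases, with a mean of -0.17 (adjusted p = 0.00110, adjusted p = 0.417 with an estimated correlation), 0.07 within series 1 and -0.35 within series 2, and Ppan had the lowest p (-0.35, SE 0.11). The mitochondrial stress and chaperone list had a mean of -0.13 with 18 of 24 lower (adjusted p = 0.00718, adjusted p = 0.384 with an estimated correlation), 0.06 and -0.28 within series 1 and 2. Phb1, a prohibitin of the inner mitochondrial membrane, had its lowest p (-0.40, SE 0.16, and -0.23 on its other probe set). The cytoskeleton and dedifferentiation list had a mean of -0.14 with 26 of 36 lower (adjusted p = 0.00843, adjusted p = 0.317 with an estimated correlation), 0.01 and -0.24 within series 1 and 2, and Vim, which encodes vimentin, was at -0.42 (SE 0.15). NF-kB and inflammation genes had a mean of -0.19 with 18 of 23 lower (adjusted p = 0.00454, adjusted p = 0.492 with an estimated correlation), -0.10 and -0.24 within series 1 and 2, and Csf1, a macrophage growth factor, was at -0.22 (SE 0.06). Adjusted over the list alone 0 members passed in any of these 4 lists. Without 10 µM array 23 the call was lost for ribosome biogenesis (-0.08, adjusted p = 0.0732) and for mitochondrial stress (-0.07, adjusted p = 0.238), and with array quality weights too (adjusted p = 0.140 and 0.226). Without DMSO array 22 it was lost for NF-kB (-0.05, adjusted p = 0.316), and without the 3 arrays of lowest quality weight for the cytoskeleton list (-0.09, adjusted p = 0.0601), which was at -0.08 without 10 µM array 23 (adjusted p = 0.0459).

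The cell cycle list was higher at 10 µM in 24 of 32 members, with a mean of 0.14 (adjusted p = 0.00186, adjusted p = 0.317 with an estimated correlation), 0.06 within series 1 and 0.21 within series 2. Ccnb2, a mitotic cyclin, had the lowest p (0.45, SE 0.12), and 0 members passed adjusted over the list alone. The hepatocyte plasma protein list had 19 of 28 members higher and a mean of 0.05 (adjusted p = 0.00448, adjusted p = 0.380 with an estimated correlation), 0.03 and 0.08 within series 1 and 2. Adjusted over the list alone 6 members passed on the higher side, among them the apolipoprotein genes Apoa2 (0.80, SE 0.23) and Apoc3 (0.78, SE 0.21). On the lower side 2 passed: Hnf4a, a hepatocyte nuclear receptor (-0.62, SE 0.20), and Apob (-0.56, SE 0.19). Acute phase protein genes had a mean of 0.13 with 17 of 22 higher (adjusted p = 0.00513, adjusted p = 0.529 with an estimated correlation), 0.01 and 0.24 within series 1 and 2. Hp, which encodes haptoglobin, was at 0.23 (SE 0.09), and 0 members passed adjusted over the list alone. Without 10 µM array 23 the acute phase call (0.03, adjusted p = 0.501) and the plasma protein call (0.03, adjusted p = 0.0631) were lost, the acute phase call was lost with array quality weights (0.04, adjusted p = 0.283), and the plasma protein mean was 0.03 without DMSO array 20 (adjusted p = 0.0138).

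The Kupffer cell and macrophage markers, which show the other main cell type of such preparations, had a mean of -0.08 at 10 µM (adjusted p = 0.779), -0.24 within series 1 and 0.08 within series 2. Their score was 1.16 in 10 µM array 23, against -0.21 ± 0.22 (SD, n = 5) in the other 10 µM arrays. The same array held the highest acute phase score of its group (0.53 against -0.01 ± 0.05).

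Among single genes, limma called 0 of 14506 at 10 µM. At an unadjusted p under 0.05 there were 1109, 555 higher and 554 lower, where 725 are expected by chance. The lowest adjusted p was 0.0833, shared by Creb5, a CREB-family transcription factor (0.69, SE 0.10), Fbxo3, a ubiquitin ligase subunit (0.59, SE 0.09), and Pop1, a subunit of RNase P (-0.63, SE 0.10). Creb5 was at 0.67 within series 1 and 0.70 within series 2. It was called with array quality weights (0.72, adjusted p = 0.0156) and after renewed quantile normalization (0.71, adjusted p = 0.0456). Without DMSO array 22 Tlr6 was called (-1.08, adjusted p = 0.0225), and without DMSO array 11 S1pr2 was (-0.88, adjusted p = 0.0482). Within series 2 alone 7 genes were called, and within series 1 alone 0, with 1693 and 773 at an unadjusted p under 0.05. At an unadjusted p under 0.05 the most negative value was that of Cd36, a fatty acid translocase (-1.65, SE 0.58), and the most positive that of Aknad1 (1.51, SE 0.39). Both lay mainly in series 2, with Cd36 at -0.38 within series 1 and -2.55 within series 2 and at -1.01 on its other probe set, and Aknad1 at 0.07 and 2.60. Serpina6, the corticosteroid-binding globulin gene, was at 1.25 (SE 0.27), 0.63 within series 1 and 1.72 within series 2. The median 95% interval of a gene reached 1.18-fold to either side.

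At 100 µM the same metabolic groups lay lower than in DMSO, by mean log2 changes down to -0.39, and no list was called higher. With an estimated correlation 0 lists were called (lowest adjusted p = 0.0609 with an estimated correlation). Kynu was at -1.50 (SE 0.29, 2.83-fold lower, n = 4 against 5), Gys2 at -1.13 (SE 0.23, 2.18-fold lower) and Sult1b1, a sulfotransferase, at -1.73 (SE 0.45, 3.31-fold lower), each past the threshold adjusted over its list alone and not over all genes (adjusted p = 0.356, 0.356 and 0.510). Of 39 lists, 12 were called by camera at the preset correlation, all lower, and fry called 0 (lowest adjusted p = 0.0611). Within series 2 alone the PPARalpha and fatty acid oxidation list passed (adjusted p = 0.0460 with an estimated correlation), the 1 list to do so in either series. At the preset correlation camera called 8 lists within series 1 alone, 7 of them lower, and 13 within series 2 alone, 12 of them lower. Of the 12 calls on all arrays, series 1 kept bile acid genes, urea cycle, gluconeogenesis, conjugation enzymes and transporters, and lost the others. The mixed form of fry called 5: PPARalpha and fatty acid oxidation, urea cycle, gluconeogenesis, transporters and hepatocyte plasma proteins. Random splits called a median of 7 lists by camera, at most 17.

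PPARalpha and fatty acid oxidation genes were lower in 30 of 35 cases, with a mean of -0.32 (adjusted p = 2.52e-10, adjusted p = 0.0630 with an estimated correlation), -0.11 within series 1 and -0.49 within series 2. Adjusted over the list alone 6 passed, all lower, among them Hadh, an enzyme of mitochondrial beta-oxidation (-0.83, SE 0.21), Cyp4a3, a fatty acid omega-hydroxylase (-0.68, SE 0.19), and Acadvl, which starts the oxidation of very long chains (-0.53, SE 0.16). The urea cycle and amino acid catabolism list had 28 of 32 members lower and a mean of -0.39 (adjusted p = 2.88e-09, adjusted p = 0.0609 with an estimated correlation), -0.17 and -0.57 within series 1 and 2, and Kynu alone passed adjusted over the list alone. Gluconeogenesis genes had a mean of -0.29 with 12 of 14 lower (adjusted p = 2.00e-05, adjusted p = 0.0609 with an estimated correlation), -0.31 within series 1 and -0.27 within series 2. Gys2 passed adjusted over the list alone, and Ppargc1a, a coactivator of fasting metabolism, was at -0.88 (SE 0.29). Lipogenesis genes had a mean of -0.12 with 15 of 21 lower (adjusted p = 0.0130, adjusted p = 0.494 with an estimated correlation), -0.11 and -0.13 within series 1 and 2. Mlxipl, the carbohydrate-response factor ChREBP, passed adjusted over that list alone (-0.57, SE 0.13). The lipogenesis call was lost without DMSO array 11 (-0.08, adjusted p = 0.105), 100 µM array 15 (-0.04, adjusted p = 0.444) or 100 µM array 27 (-0.06, adjusted p = 0.179), and the mean was -0.20 without 100 µM array 16 and -0.19 without 100 µM array 26. It was also lost with dim genes left out (adjusted p = 0.0929) and with array quality weights (-0.06, adjusted p = 0.203).

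CAR and PXR targets were lower in 21 of 24 cases, with a mean of -0.38 (adjusted p = 1.13e-06, adjusted p = 0.0630 with an estimated correlation), -0.14 and -0.56 within series 1 and 2. Aldh1a1, a retinal dehydrogenase, had the lowest p of that list (-0.74, SE 0.21), and 0 members passed adjusted over the list alone. The conjugation enzymes had a mean of -0.27 with 19 of 25 lower (adjusted p = 0.000209, adjusted p = 0.0630 with an estimated correlation), -0.18 and -0.33 within series 1 and 2, and Sult1b1 passed adjusted over the list alone. Efflux and uptake transporters had a mean of -0.30 with 19 of 23 lower (adjusted p = 6.47e-06, adjusted p = 0.0609 with an estimated correlation), -0.18 and -0.38 within series 1 and 2. Bile acid genes had a mean of -0.27 with 19 of 24 lower (adjusted p = 1.11e-05, adjusted p = 0.0609 with an estimated correlation), -0.23 and -0.30 within series 1 and 2. Slco1b2 passed adjusted over the list alone in both (-0.81, SE 0.16), and Abcb4, the phospholipid exporter of bile, was at -0.53 (SE 0.17).

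Complement and coagulation genes were lower in 23 of 28 cases at 100 µM, with a mean of -0.28 (adjusted p = 1.26e-05, adjusted p = 0.143 with an estimated correlation), -0.13 and -0.40 within series 1 and 2. The only member past the threshold adjusted over the list alone lay on the other side: Plg, which encodes plasminogen, at 0.38 (SE 0.09). NF-kB and inflammation genes had a mean of -0.32 with 20 of 23 lower (adjusted p = 1.26e-05, adjusted p = 0.257 with an estimated correlation), -0.09 and -0.52 within series 1 and 2, and -0.19 without DMSO array 22 (adjusted p = 0.00565). The mitochondrial stress and chaperone list had a mean of -0.16 with 21 of 24 lower (adjusted p = 0.00113, adjusted p = 0.273 with an estimated correlation), -0.07 and -0.21 within series 1 and 2. Csf1 (-0.21, SE 0.07) and Ppargc1a had the lowest p of these, and 0 members of either passed adjusted over the list alone. Kupffer cell and macrophage markers moved with these groups at 100 µM, with a mean of -0.27 and 18 of 20 lower (adjusted p = 0.00845, adjusted p = 0.852 with an estimated correlation), 0.05 within series 1 and -0.58 within series 2. Cd163, a scavenger receptor of macrophages, was at -1.05 (SE 0.62), while Cd68, a lysosomal macrophage marker, was at 1.18 (SE 0.42), and 0 members passed adjusted over the list alone. Cd68 was at 0.31 within series 1 and 1.80 within series 2, and its DMSO level was 10.01 in series 1 and 7.33 in series 2. The macrophage call was lost without DMSO array 10 (-0.20, adjusted p = 0.107), DMSO array 21 (-0.15, adjusted p = 0.125), 100 µM array 26 (-0.21, adjusted p = 0.0933) or 100 µM array 27 (-0.11, adjusted p = 0.237), and with dim genes left out (-0.24, adjusted p = 0.189), and the mean was -0.41 without 100 µM array 15 (adjusted p = 0.000416).

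Limma called 0 genes at 100 µM over all 14506, with 993 at an unadjusted p under 0.05, 497 higher and 496 lower, where 725 are expected by chance. The lowest adjusted p was 0.356, for Creb5 (0.65, SE 0.12), Dhrs3, a retinal reductase (-0.80, SE 0.15), and Aqp8, a water channel (-1.33, SE 0.25), among others. Dhrs3 was at -0.79 within series 1 and -0.81 within series 2, and Aqp8 at -0.68 and -1.89. Cd36 was at -1.73 (SE 0.64), 0.34 within series 1 and -3.43 within series 2, with -1.14 on its other probe set. Within series 2 alone 1 gene was called, Aknad1 (2.65, adjusted p = 0.0270), and within series 1 alone 0. Those fits had 977 and 909 genes at an unadjusted p under 0.05.

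**Figure D1:**
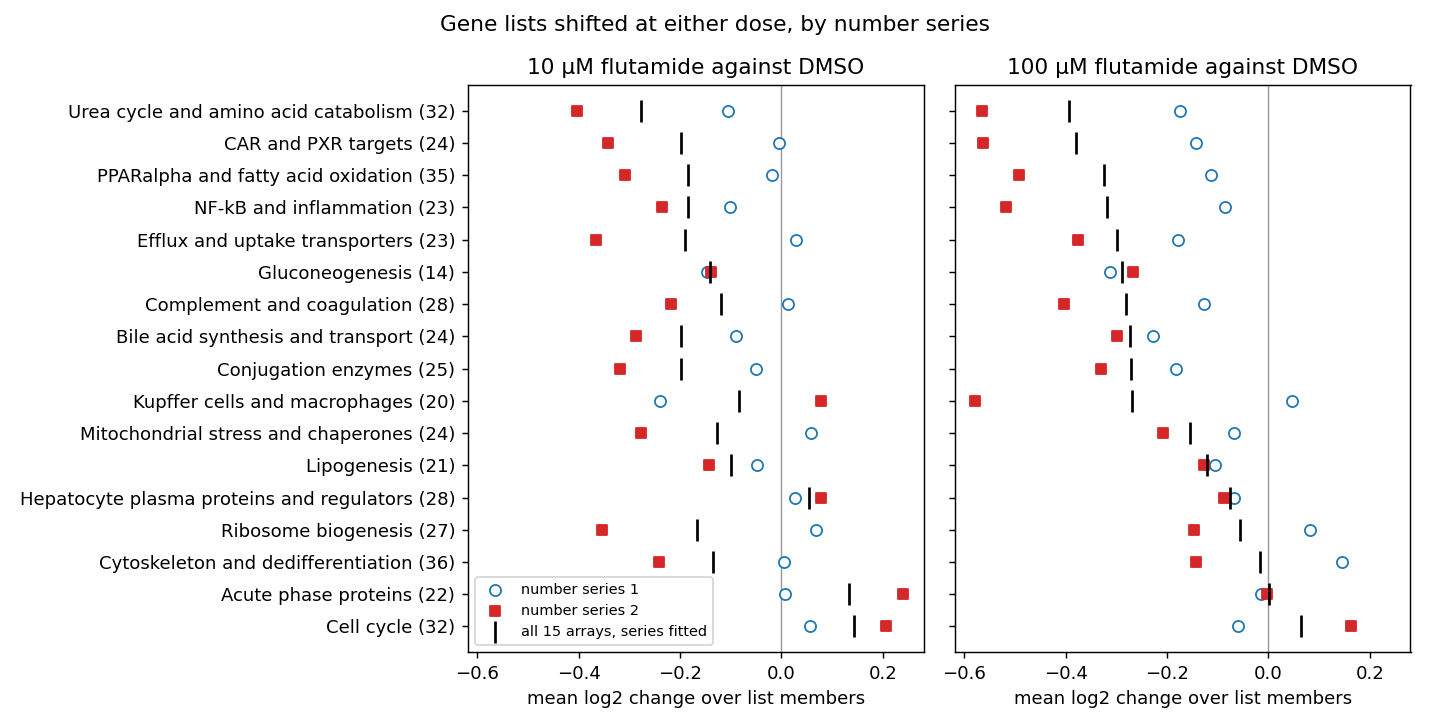
Mean log2 change over the members of each of the 17 gene lists called at either dose (x axis), at 10 µM (left) and 100 µM (right) against DMSO, with the number of measured members after each list name. Open circles are number series 1, filled squares series 2 and bars the fit to all 15 arrays; the urea cycle list lies at -0.17 in series 1 and -0.57 in series 2 at 100 µM.

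Lists called at 1 dose had the following values at the other dose. At 100 µM the cell cycle list averaged 0.06 (adjusted p = 0.345), ribosome biogenesis -0.06 (0.230), the cytoskeleton list -0.02 (0.482), hepatocyte plasma proteins -0.08 (0.555) and acute phase proteins 0.00 (0.903). At 10 µM complement and coagulation averaged -0.12 (adjusted p = 0.355) and lipogenesis -0.10 (0.0908). Adjusted over the list alone, 2 members passed at 10 µM: Agpat2, an enzyme of glycerolipid synthesis (-0.88, SE 0.23), in the lipogenesis list, and Plg (0.38, SE 0.08) in the complement list. Agpat2 was at -0.37 within series 1 and -1.27 within series 2.

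Apart from mitochondrial stress, the stress-response lists were called at neither dose. The ATF4 and CHOP targets of the integrated stress response averaged -0.03 at 10 µM and 0.00 at 100 µM (adjusted p = 0.847 and 0.729). Adjusted over the list alone, Gdf15, a stress-induced hormone (0.62, SE 0.13), was higher and Phgdh, of serine synthesis (-0.39, SE 0.09), and Atf5 (-0.58, SE 0.17) were lower at 10 µM, and Phgdh was lower at 100 µM (-0.44, SE 0.10). ER stress chaperones averaged 0.02 and -0.01 (0.847 and 0.618). NRF2 targets of the oxidative stress response averaged -0.12 and -0.07 (0.187 and 0.375), and Srxn1, a sulfiredoxin, passed adjusted over the list alone at 10 µM (0.47, SE 0.11). AhR targets averaged -0.08 and -0.05 (0.944 and 0.986), p53 targets -0.03 and 0.02 (0.847 and 0.640), and heat shock genes 0.07 and -0.01 (0.847 and 0.482). Apoptosis genes averaged -0.05 and -0.08 (0.327 and 0.162), the proteasome -0.04 and 0.02 (0.263 and 0.774), and autophagy and lysosome genes 0.05 and 0.02 (0.253 and 0.986). Immediate early genes averaged 0.03 and -0.02 (0.327 and 0.650).

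Respiratory complex I averaged -0.03 at 10 µM and -0.06 at 100 µM (adjusted p = 0.872 and 0.159), and complexes II to V -0.04 and -0.04 (0.495 and 0.140). Atp5mc1, an ATP synthase subunit, passed adjusted over the latter list alone at 10 µM (-0.44, SE 0.09). Glycolysis and hypoxia genes averaged -0.07 and -0.04 (0.185 and 0.574), with Egln3, an oxygen-sensing hydroxylase, past the threshold adjusted over the list alone at 100 µM (-0.66, SE 0.16). Cholesterol synthesis averaged -0.04 and -0.05 (0.847 and 0.412), aminoacyl-tRNA synthetases -0.14 and -0.07 (0.0536 and 0.375), circadian clock genes 0.02 and -0.00 (0.847 and 0.640), and androgen-related and sex-biased genes 0.07 and -0.11 (0.847 and 0.105). Among markers of other cell types, endothelial cells averaged -0.04 and -0.04 (0.255 and 0.345), stellate cells and fibroblasts -0.01 and 0.04 (0.904 and 0.357), cholangiocytes -0.02 and 0.01 (0.904 and 0.735), lymphocytes -0.02 and 0.04 (0.877 and 0.375), and red blood cells 0.01 and 0.08 (0.904 and 0.345). The mean, median and test differed in sign in 5 lists at 10 µM (p53 targets, heat shock, stellate cells, cholangiocytes and red blood cells) and in 4 at 100 µM (AhR targets, ATF4 and CHOP targets, acute phase proteins and immediate early genes), and in 0 of the called lists.

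Of the fixed genes, Ddit3, which encodes the stress factor CHOP, had the most positive value. It was at 9.30 ± 0.87 (SD, n = 6) at 10 µM, 9.14 ± 0.80 (n = 4) at 100 µM and 8.23 ± 0.60 (n = 5) in DMSO, or log2 changes of 1.14 (SE 0.37) and 0.98 (SE 0.41), with limma adjusted p = 0.447 and 0.708. Cdkn1a, the p53-responsive cell cycle inhibitor, was at 0.37 (SE 0.16) and 0.41 (SE 0.17), with adjusted p = 0.597 and 0.708. Cyp2b1, the classical CAR target, was at -1.24 (SE 0.65) and -1.71 (SE 0.72), with -0.11 and -0.47 within series 1 and -2.09 and -2.67 within series 2. Cyp1a1 and Cyp1a2, the main AhR targets, were at -0.30 (SE 0.39) and 0.36 (SE 0.21) at 10 µM and at -0.07 and 0.13 at 100 µM. The sign of Cyp1a1 turned without 10 µM array 23 (0.15) and without 100 µM array 15 (0.19). Cyp3a23-3a1, a PXR target, was at -0.05 and -0.28, and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, at 0.07 and -0.02. The level of Cyp7a1 was 3.53 at 10 µM, 3.44 at 100 µM and 3.47 in DMSO. The median of 1052 olfactory receptor genes, taken as silent here, was 3.53. Changes of Cyp7a1 therefore lie near the floor and do not tell whether it responds. Hmox1 and Nqo1, oxidative stress genes, were at 0.23 and -0.06 at 10 µM and at -0.19 and 0.15 at 100 µM. Without 10 µM array 23, Hmox1 was at -0.09, Nqo1 at 0.16 and Cyp7a1 at -0.19 at 10 µM. Hmox1 was at -0.05 at 10 µM without DMSO array 22 and at 0.34 at 100 µM without 100 µM array 26. Hspa5, the ER chaperone BiP, was at 0.18 and 0.06, Alb at 0.10 and 0.07, and Ccnd1, a G1 cyclin, at -0.09 and -0.13. Small values turned in sign without single arrays: Cyp3a23-3a1 at 10 µM without 10 µM array 12 or 24 (0.03 each), Ccnd1 at 10 µM without DMSO array 21 (0.01), Cyp7a1 at 10 µM without 10 µM array 14 (-0.01), and Cyp7a1 at 100 µM without DMSO array 10, 11 or 22 or 100 µM array 26 or 27 (0.00 to 0.04). None of these 12 genes passed the limma test over all genes at either dose.

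**Figure D2:**
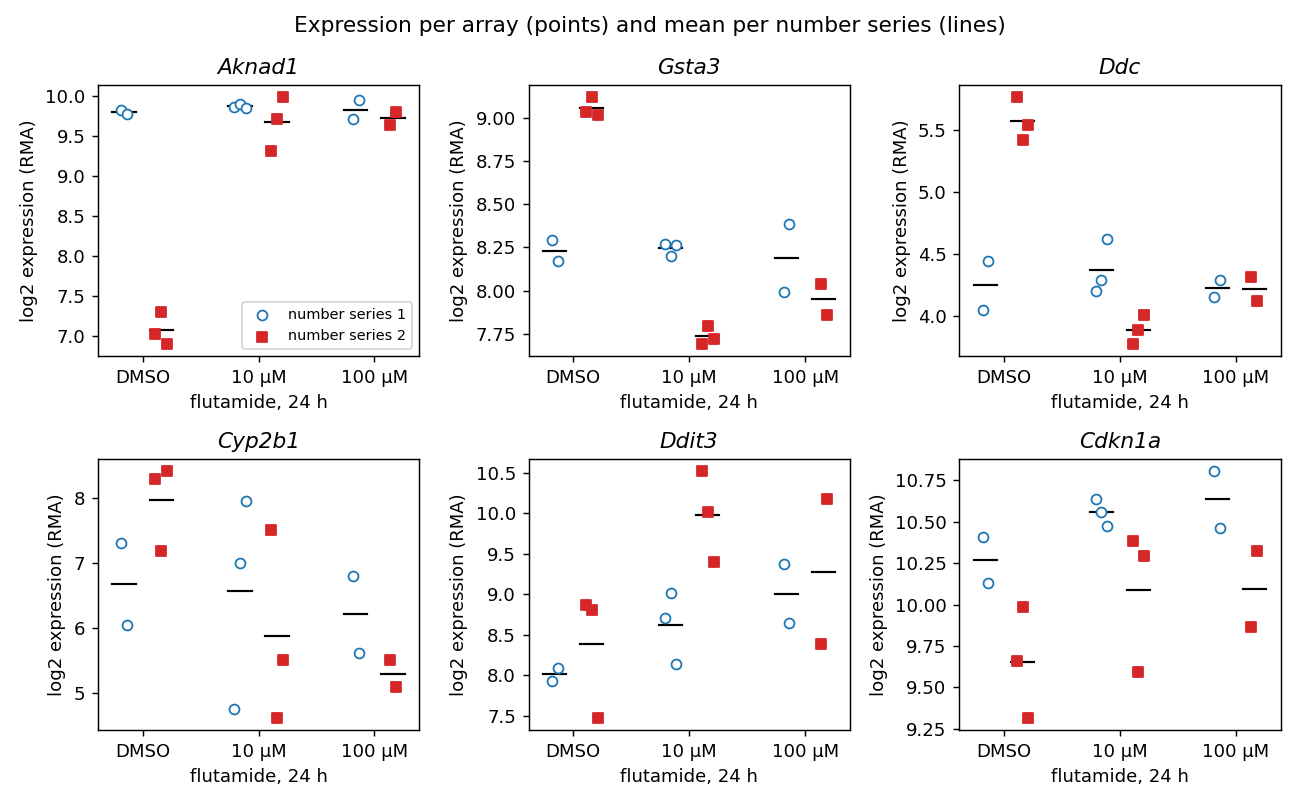
Log2 expression (y axis) of 6 genes on each of the 15 arrays, by flutamide dose for 24 h (x axis), with open circles for number series 1, filled squares for series 2 and a line at the mean of each series. Aknad1 lies at 6.90 to 7.30 on DMSO arrays 20 to 22 and at 9.32 to 9.99 on the other 12 arrays.

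Between 100 and 10 µM, the secreted-protein groups of hepatocytes lay lower at the higher dose by camera at the preset correlation, and 0 lists were called with an estimated correlation (lowest adjusted p = 0.619 with an estimated correlation). Without the 3 arrays of lowest quality weight these calls were lost, for plasma proteins (-0.04, adjusted p = 0.178), complement (-0.07, adjusted p = 0.148) and acute phase genes (0.02, adjusted p = 0.922). In that fit androgen-related genes were at 0.04 (adjusted p = 0.922), macrophage markers at 0.05 (0.922), gluconeogenesis at -0.01 (0.663), CAR and PXR targets at -0.13 (0.118) and urea cycle genes at -0.11 (0.0798), none of them called. Hepatocyte plasma protein genes had a mean of -0.13 with 27 of 28 members lower (adjusted p = 2.57e-05, adjusted p = 0.619 with an estimated correlation), -0.09 within series 1 and -0.17 within series 2, and F2, which encodes prothrombin, was at -0.25 (SE 0.12, n = 4 against 6). Complement and coagulation genes had a mean of -0.16 with 25 of 28 lower (adjusted p = 0.000482, adjusted p = 0.619 with an estimated correlation), -0.14 and -0.18 within series 1 and 2, and acute phase genes a mean of -0.13 with 20 of 22 lower (adjusted p = 0.00475, adjusted p = 0.619 with an estimated correlation), -0.02 and -0.24. PPARalpha and fatty acid oxidation had a mean of -0.14 with 25 of 35 lower (adjusted p = 0.00475, adjusted p = 0.619 with an estimated correlation), -0.09 and -0.18 within series 1 and 2, and Ppara itself, the receptor gene, was at -0.66 (SE 0.28). Gluconeogenesis had a mean of -0.15 with 10 of 14 lower (adjusted p = 0.0343, adjusted p = 0.619 with an estimated correlation), -0.17 and -0.13, with Gys2 at -0.65 (SE 0.22). The androgen-related and sex-biased list had a mean of -0.18 with 11 of 15 lower (adjusted p = 0.0343, adjusted p = 0.619 with an estimated correlation), -0.09 and -0.28, with Hsd17b6, an androgen-metabolising dehydrogenase, at -0.54 (SE 0.28, and -0.09 and -0.42 on its other probe sets). CAR and PXR targets had a mean of -0.18 with 16 of 24 lower (adjusted p = 0.0361, adjusted p = 0.619 with an estimated correlation), -0.14 and -0.22, and urea cycle genes a mean of -0.11 with 22 of 32 lower (adjusted p = 0.0361, adjusted p = 0.619 with an estimated correlation), -0.07 and -0.16. Kupffer cell and macrophage markers moved with these lists, with a mean of -0.18 and 16 of 20 lower (adjusted p = 0.0343, adjusted p = 0.723 with an estimated correlation), but were at 0.29 within series 1 and -0.66 within series 2.

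All 9 lists called between the doses were lower at 100 µM, and the other 30 had adjusted p between 0.0638 and 0.943. Fry called 0 (lowest adjusted p = 0.620), while random splits called a median of 7 by camera. The mean, median and test differed in sign in 6 lists (ATF4 and CHOP targets, mitochondrial stress, lipogenesis, cholesterol synthesis, conjugation enzymes and endothelial cells), 0 of them called. Single arrays moved the count of 9 lists to 2 without 100 µM array 27, to 5 without 100 µM array 15 and to 5 without 10 µM array 23. Leaving out 100 µM array 27 lost the calls of CAR and PXR targets (adjusted p = 0.374), acute phase proteins (0.0865), fatty acid oxidation (0.186), complement (0.0574), urea cycle genes (0.607), gluconeogenesis (0.186), androgen-related genes (0.186) and macrophage markers (0.390). In this order, the means without that array were -0.11, -0.09, -0.09, -0.11, -0.02, -0.12, -0.13 and -0.03. With 100 µM array 15 left out, the calls of CAR and PXR targets (0.124), fatty acid oxidation (0.0740), gluconeogenesis (0.352) and androgen-related genes (0.225) were lost. The means of these lists were then -0.17, -0.10, -0.06 and -0.11. Without 10 µM array 23 the mean of the macrophage list was 0.06 (adjusted p = 0.908) and that of the acute phase list -0.03 (0.242), and CAR and PXR targets (0.131), urea cycle genes (0.216), gluconeogenesis (0.0806) and androgen-related genes (0.163) were not called. Without 10 µM array 14 the calls of CAR and PXR targets (adjusted p = 0.287), urea cycle genes (0.149), gluconeogenesis (0.149) and androgen-related genes (0.0729) were lost. Without 100 µM array 26 the macrophage call was lost (adjusted p = 0.167), and its mean was -0.31 without 10 µM array 25 and -0.33 without 100 µM array 15. Without 100 µM array 16 the means of fatty acid oxidation (-0.23) and complement (-0.25) were more negative. Other fits also ended calls. Renewed quantile normalization did so for CAR and PXR targets (adjusted p = 0.0764), urea cycle genes (0.0975), gluconeogenesis (0.0764) and androgen-related genes (0.0557). The means of these lists were then -0.18, -0.11, -0.15 and -0.18. Leaving out dim genes ended those of CAR and PXR targets (0.0626), urea cycle genes (0.0626), androgen-related genes (0.0712) and macrophage markers (0.0774). Here the means were -0.19, -0.12, -0.20 and -0.18. Array quality weights ended the calls of CAR and PXR targets (0.0823), urea cycle genes (0.110), gluconeogenesis (0.263), androgen-related genes (0.286), acute phase proteins (0.335) and macrophage markers (0.758). With these weights the means were -0.14, -0.09, -0.06, -0.05, -0.02 and 0.03. A random block ended the call of CAR and PXR targets (-0.18, adjusted p = 0.0508). Limma called 0 genes between the doses, with 723 at an unadjusted p under 0.05 where 725 are expected by chance, and with 481 without 100 µM array 15, 1004 without 100 µM array 16 and 1078 without 10 µM array 23. Also, 0 members of any list passed adjusted over the list alone. The lowest adjusted p was 0.321, for Or5ac22, an olfactory receptor gene at a level of 4.24 ± 0.13 at 100 µM and 3.64 ± 0.19 at 10 µM. Interferon-inducible Ifitm2 (-1.49, SE 0.52) and Ifit3 (-1.31, SE 0.45) had the most negative changes at an unadjusted p under 0.05.

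The response to flutamide was then compared between the number series. At 10 µM 6 genes differed in response by the interaction test, and at 100 µM 1 did. Aknad1 had a log2 change of 0.07 in series 1 and 2.60 in series 2 at 10 µM (difference 2.53, SE 0.23, adjusted p = 0.00203), and 0.03 and 2.65 at 100 µM (difference 2.62, SE 0.26, adjusted p = 0.00416). Gsta3 (difference -1.33, adjusted p = 0.0116), Ddc, which encodes the aromatic amino acid decarboxylase (-1.81, adjusted p = 0.0116), the RNA helicase genes Ddx21 (-1.02, adjusted p = 0.0343) and Dhx9 (-1.43, adjusted p = 0.0423), and Ndufaf4, a complex I assembly factor (-0.93, adjusted p = 0.0490), differed at 10 µM. In each of the 6, DMSO arrays 20 to 22 lay outside the range of the other 12 arrays. Gsta3 was at 9.06 ± 0.05 (SD, n = 3) on these and at 8.06 ± 0.24 (n = 12) on the others. Ddc was at 5.58 ± 0.18 (n = 3) on these and at 4.18 ± 0.24 (n = 12) on the others. The latter level lies below the 95th percentile (5.20) of the olfactory receptor genes taken as silent, so Ddc was near the floor on those arrays. Counted over both doses together, the 6 genes became 116 without 10 µM array 25 and 27 without 100 µM array 16 (8 at 10 µM and 22 at 100 µM). The count moved to 2 without DMSO array 10 or 10 µM array 12 or 14, and to 3 without DMSO array 11, 20 or 22, 10 µM array 13 or 24, or 100 µM array 27. Without 100 µM array 26 it was 3 at 10 µM and 2 at 100 µM. The count of 1 at 100 µM was also 3 without 10 µM array 23, and 2 without DMSO array 21 or 100 µM array 15. The Aknad1 call at 100 µM was lost without DMSO array 10 or 100 µM array 27. Among lists, 9 differed between the series at 10 µM, 11 at 100 µM and 7 between the doses by camera, and 0 with an estimated correlation.

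The changes at both doses were last set against each other. Across genes, which are not independent replicates, the log2 changes at 10 and 100 µM had a Pearson correlation of 0.634 and a covariance of 0.0240. Both use the same DMSO arrays, and unchanged groups simulated against shared controls gave a mean correlation of 0.495 (highest 0.518 of 100) and a covariance of 0.0138, which leaves a difference in covariance of 0.0103. The simulated noise was independent between genes, and the jackknife SE of the correlation over the 15 arrays was 0.166, more than the distance between 0.634 and 0.495. With no shared array, the correlation was -0.00635 between 10 µM in series 1 and 100 µM in series 2, and 0.0576 the other way round. Within series 1 it was 0.392 and within series 2 0.671. Signs were the same for 68.7% of genes, against 66.5% simulated. At an unadjusted p under 0.05 in both, 130 genes were higher and 195 lower at both doses, where independent lists give 19.0 and 18.9, and 325 in all against a simulated mean of 165.25 (highest 201). Of the 39 lists 9 were called lower at both doses and 0 higher at both by camera at the preset correlation, and with an estimated correlation 0 were called at either dose. Both doses are set against the same 5 DMSO arrays, and no value for unchanged groups was simulated for lists.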

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

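The tests of the series 2 pattern, of the macrophage share and of both explanations of the genes that differ between the number series were chosen only after the results were seen, as were the levels of olfactory receptor genes, the splits within each series and the look at which arrays made up the random splits, and those of the hepatocyte share, of RNA made by the same macrophages and of random splits were set before.

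Of the lists called against DMSO, 13 of 14 at 10 µM and 11 of 12 at 100 µM had the larger mean change in number series 2, with gluconeogenesis the exception at both doses and lipogenesis at 100 µM close (-0.11 and -0.13), and with an estimated correlation 0 lists differed between the series. Among 68 genes more than 1 log2 unit from DMSO at both doses within series 2 (13 higher, 55 lower), the median ratio of the series 1 change to the series 2 change was 0.0865 (95% bootstrap interval 0.0243 to 0.134), and in 39 (57.4%) the flutamide mean of series 2 lay within the range of series 1, against 10 (14.7%) for the mean of DMSO arrays 20 to 22. These genes were chosen for their distance from DMSO arrays 20 to 22, which favours both values, so neither excludes a flutamide effect shared by the series nor shows that these 3 controls differ for another reason. The interaction test argues against an equal effect in both series only for its 6 genes at 10 µM and for Aknad1 at 100 µM. Of these calls, Aknad1 at 10 µM was kept whichever array was left out. Each of the other calls was lost without DMSO array 10 or without DMSO array 11, so for them an equal effect is not excluded. On all genes, 2 of 455 sets of 3 arrays lay outside the other 12 on as many genes (471 here, 496 for 10 µM array 23 with 100 µM arrays 15 and 27), and a response that depends on the cells of the series stays open too, since the correlation of 0.671 between the doses within series 2 rests on the same DMSO arrays.

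Kupffer cell and macrophage markers vary together between arrays, with an estimated inter-gene correlation of 0.499. This value restates the pattern, so a different share of macrophages per biochip stays open. A different share of hepatocytes could lower or raise all other cell types together, and the lowest correlation of another score with the macrophage score was -0.39 (cholangiocytes, bootstrap interval -0.70 to -0.06), which met the bound set beforehand against it. The explanation is left open because 9 of the 12 cholangiocyte genes lay at or below the 95th percentile (5.20) of 1052 olfactory receptor genes, taken as silent here, and the other 3 gave -0.50 (-0.83 to 0.25), although the 2 lymphocyte genes above that level gave -0.49 (-0.76 to -0.08). Over all measured members, correlations with the macrophage score were positive for endothelial cells (0.78, bootstrap interval 0.08 to 0.94) and stellate cells and fibroblasts (0.59, -0.49 to 0.90). They were also positive for lymphocytes (0.34, -0.33 to 0.75) and hepatocyte plasma proteins (0.39, -0.31 to 0.73). All of these intervals but the endothelial one held both signs. Without 10 µM array 23 the correlations were, in this order, 0.51, 0.07, 0.11 and 0.13. RNA made by the same macrophages in different amounts may also give the range of 1.75 log2 units in the score, and no count of cells was analysed here to separate these.

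The genes that differ between the number series number 79, with 4 of 35 tested RT1 genes among them (Fisher exact p = 3.75e-05), which is consistent with hepatocytes of different animals or strains. The RT1 genes lie close together in the genome and share sequence, so they are not independent draws. A batch of labelling or hybridisation could also add to the 79 genes, and the 2 are not separated here.

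The test of each pattern was repeated on 100 splits of the arrays, the real one included. Group labels were exchanged at random among the arrays of the 2 groups compared, whatever their series, or series labels within each group for the differences between series. With a real count of 0 called genes every split gives at least as many (100 of 100 in each comparison; highest others 1, 3 and 119), so that count is not informative. With flutamide at 10 µM, 14 splits had as many genes at an unadjusted p under 0.05 (1109; highest other 1890) and 5 as many lists (14; highest other 17), so chance could give these counts. With flutamide at 100 µM, the numbers were 14 (993; 1894) and 30 (12; 17), and between the doses 43 (723; 2870) and 41 (9; 19), so chance is not excluded for any of them. With labels exchanged within each series alone, as many genes at an unadjusted p under 0.05 and as many lists came from 11 and 7 of 100 splits at 10 µM, 5 and 18 of 60 at 100 µM, and 44 and 43 of 100 between the doses, so chance is not excluded there either. The split that called 119 genes set arrays 24 to 27 of series 2 against array 23 and all flutamide arrays of series 1, and the next one, with 64 genes, set 10 µM arrays 23 and 24 and 100 µM arrays 15 and 27 apart. In the split with 119 genes all series 1 flutamide arrays carry 1 label. With the series fitted, that split draws on array 23 and on the DMSO arrays of both series. A flutamide change that differs between the series can therefore enter it, and what gave its 119 genes was not tested. The split with 64 genes holds the 3 arrays of lowest quality weight on 1 side, a structure of these samples other than dose. For the 79 genes that differ between series only the real split gave as many (highest other 1), so chance is unlikely for these. For the genes that respond differently between series, 2 splits gave as many (6, highest other 27). Exchanging series labels also mixes the differences between the series into the spread within groups. These splits therefore cannot decide whether chance gave the 6 genes.

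A rule for single arrays far from their group picked 13 values in 153 tests, where chance gives about 1 in 20, or 7.65. Of these, 9 were on 10 µM array 23: scores of NRF2 targets (-0.42), acute phase proteins (0.53), proteasome (-0.39), ribosome biogenesis (-0.48), stellate cells (0.24), Kupffer cells and macrophages (1.16) and endothelial cells (0.32), and the levels of Cyp1a1 (8.81) and Nqo1 (10.78). The others were the cholangiocyte score (0.0699) and Cdkn1a (9.59) on 10 µM array 24, the aminoacyl-tRNA synthetase score on 100 µM array 15 (-0.0537) and the proteasome score on 100 µM array 26 (-0.0344).

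The difference of the flutamide change, series 2 minus series 1, was 2.53 for Aknad1, -1.81 for Ddc, -1.02 for Ddx21, -1.43 for Dhx9, -1.33 for Gsta3 and -0.93 for Ndufaf4 at 10 µM, and 2.62 for Aknad1 at 100 µM. Lists differed at 10 µM by -0.34 (CAR and PXR targets), -0.29 (NRF2 targets), -0.26 (ATF4 and CHOP targets), -0.57 (aminoacyl-tRNA synthetases), -0.34 (mitochondrial stress), -0.29 (PPARalpha and fatty acid oxidation), -0.40 (transporters), -0.14 (proteasome) and -0.42 (ribosome biogenesis). At 100 µM the differences were -0.42 (CAR and PXR targets), -0.27 (aminoacyl-tRNA synthetases), -0.43 (NF-kB), 0.13 (respiratory complexes II to V), -0.38 (PPARalpha and fatty acid oxidation), -0.28 (complement), -0.39 (urea cycle), 0.22 (cell cycle), -0.25 (heat shock), -0.29 (cytoskeleton) and -0.23 (ribosome biogenesis). With an estimated correlation 0 of these list differences passed.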

How the results depend on the processing

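The tests without the 3 arrays of lowest quality weight were chosen only after the result was seen, and the other alternatives were fixed before. Genes called at 10 µM numbered 7 within number series 2, 1 when quantile-normalized again, 1 with array quality weights and 0 to 1 leaving out each array in turn, against 0. At 100 µM there was 1 within series 2, the same gene was called at both doses there (1), and leaving out each array gave 0 to 0, as it did between the doses and for genes called at both doses. Lists at 10 µM numbered 7 within series 1, of which 2 were lower against 11 in all arrays, 0 with an estimated correlation, 0 by fry and 13 to 16 leaving out each array, against 14. The 7 lists within series 1 were not among these 14. Without 10 µM array 23 the count was 13, although the calls of acute phase proteins, mitochondrial stress, plasma proteins and ribosome biogenesis were lost. At 100 µM the lists numbered 0 with an estimated correlation (1 within series 2), 0 by fry and 10 to 14 leaving out each array, against 12. Between the doses the lists numbered 4 with array quality weights, 4 without the 3 arrays of lowest weight, 0 with an estimated correlation, 0 by fry and 2 to 13 leaving out each array, against 9. All these counts take in any list called in a fit, so they do not count how many of the original calls were kept. Of the 9, fatty acid oxidation alone kept its call without the 3 arrays. With array weights fatty acid oxidation, plasma proteins and complement kept theirs. Genes that respond differently between series numbered 3 when quantile-normalized again, 2 with dim genes left out, 2 with an intensity trend, 35 with array weights, 1 at an adjusted p under 0.01 and 2 to 116 leaving out each array, against 6. The correlation between doses was 0.392 within series 1, -0.00635 and 0.0576 between different series, and 0.552 to 0.717 leaving out each array. Within series 1 at 10 µM the direction was reversed for CAR and PXR targets (-0.00477, by the test alone), mitochondrial stress (0.0589), transporters (0.0291), the cytoskeleton list (0.00521) and ribosome biogenesis (0.0682). Between the doses it was reversed for macrophage markers (0.29 within series 1, 0.0540 without the 3 arrays of lowest weight) and acute phase proteins (0.0227 without those arrays). Without those arrays the mean of androgen-related genes also turned (0.0351), while that of gluconeogenesis was -0.00899. Without the 3 arrays of lowest weight the 10 µM calls of acute phase proteins (adjusted p = 0.804), mitochondrial stress (0.789), plasma proteins (0.384), transporters (0.113), the cytoskeleton list (0.0601) and ribosome biogenesis (0.804), and the 100 µM call of lipogenesis (0.512), were lost. The cause of these differences was not tested, except that correlations between different series share no DMSO array by construction. The correlation was not computed for the fits of 2 groups alone or with the intensity trend. No paired analysis was possible because the groups share no replicate numbers.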

Other observations

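The tests of genes between the number series described here were chosen only after the result was seen, and the genes named were picked after their values were seen. Between the number series, with dose fitted, 79 genes differed, 33 higher and 46 lower in series 2. Timd2, which encodes a TIM-family cell surface receptor, was lower in series 2 (-1.31, SE 0.08, adjusted p = 1.33e-06), as were Gpx2, a glutathione peroxidase (-2.52, SE 0.19, adjusted p = 8.73e-06), and Pla1a, a secreted phospholipase (-1.62, SE 0.13, adjusted p = 3.20e-05). Phlda1 was higher (1.37, SE 0.19, adjusted p = 0.00566), as was Ces2e, a carboxylesterase (0.86, SE 0.12, adjusted p = 0.00566).

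Of 35 tested RT1 genes, which encode the rat major histocompatibility antigens, 4 were lower in series 2: RT1-N2 (-2.25, SE 0.15), RT1-CE5 (-2.12, SE 0.19), RT1-CE7 (-0.42, SE 0.08) and RT1-O1 (-0.62, SE 0.13). These loci differ between rat strains and animals, and the enrichment (Fisher exact p = 3.75e-05) is consistent with cells of different animals in the 2 series. If so, each series may be 1 isolation of cells, and the arrays within it may share an animal. Random splits gave at most 1 gene against the 79.

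Aknad1 was at 7.07 ± 0.20 on DMSO arrays 20 to 22 and at 9.78 ± 0.18 on the other 12 arrays. Measuring it by quantitative PCR in these and other controls of the same cell isolation would show whether the 3 controls stand apart.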
